A study of Bombus terrestris with 16 samples.

How the data were processed

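Poly(A) RNA from the guts of Bombus terrestris workers was sequenced by the authors on an Illumina HiSeq 2000 after random-hexamer priming, per the labels. The 16 libraries came from 4 colonies (K, L, S and T) crossed with 4 exposures: a control and Crithidia bombi genotypes 068, 075 and 161. Each library was a pool of 3 workers aged 7 d and killed 18 h after exposure, so spread between workers was not measured. The submitters' notes name TopHat 1.9. The counting program, genome build, annotation release and any filter are not stated.

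The deposited table gives, per the file headers, a read count and an RPKM, a count scaled by gene length and library total, for each of 10635 RefSeq transcript records in each library. The deposited count columns hold whole numbers, and in 16 of 16 the sum equals the library total in the header. The deposited RPKM values equal count, length and total combined by the usual formula in 151539 of 151539 nonzero cells (relative tolerance 1e-06). Counts from 1 to 9 were even in 69.1% of cases, against 49.6% of counts from 200 to 999, a pattern that counting both mates of a pair gives. If both mates were counted, which was not tested, low counts hold fewer independent fragments than their size. Library totals ran from 8.47 to 9.29 M reads, and 3 counts, the limit that a count of 0 allows, correspond to 0.295 to 0.415 CPM after scaling. This limit covers counting error only, takes reads as independent, and is too low if both mates were counted. The 16 coverage columns were not used.

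Genes were named by the KEGG description deposited with each record, where its hit score was at least 100 (6569 of 8120 described genes). This minimum was set after the annotation and exploratory fits of single genes had been seen. Symbols came from a RefSeq gene table that matched 5155 records at 4923 loci; 450 records share a locus with another, so they are not always separate genes. Records are called genes here.

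Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr count filter (8406 genes kept), and the quasi-likelihood F-test with colony and exposure as factors (9 residual degrees of freedom). The common biological coefficient of variation was 0.282. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Contrasts were exposed against control, each genotype against control, the genotypes with each other, and the colonies. The interaction of colony with exposed state used the 3 exposed libraries of a colony as its replicates (8 residual degrees of freedom). CPM values were scaled by TMM.

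Response similarity was the mean Pearson correlation across genes of changes from the colony's own control, on log2(RPKM + 1) of 7553 genes with mean RPKM of at least 1, for the same against different genotypes in pairs of colonies. Its test was a one-sided exact permutation of genotype labels over 216 relabellings. Sums of squares were split by colony and exposure, with 100 relabellings. Principal components used log2 CPM with a prior count of 2.

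Gene lists were fixed as patterns on the product description: antimicrobial peptides, lysozymes and transferrins, pathogen recognition, the Toll, Imd, JAK/STAT and JNK pathways, melanisation and serpins, RNA interference, apoptosis and autophagy, oxidative defence, gut lining, digestive proteases, digestive carbohydrases and lipases, detoxification, chaperones, the secretory pathway, ribosomal proteins, mitochondrial energy metabolism, proteasome and ubiquitin, odorant-binding, nutrient transport, lipid metabolism, epithelial renewal, cell cycle, circadian clock, cuticle, and markers of muscle, hemocytes, nervous system, germ line, fat body, Malpighian tubule and glands. Lists with at least 5 tested members were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. No description matched the antimicrobial peptide, cuticle and fat body lists, and the gland list had 1 gene that was not tested. After the data were seen, 6 matches by spelling only were removed, and a list of immune terms and the annotated processes with at least 10 tested genes were added. List members among called genes were counted by Fisher's exact test against the described genes tested.

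The genes named were chosen by a fixed rule. They were the described genes past the threshold, up to 12 per F-test by adjusted p and up to 12 in each direction for exposure (6 for a genotype) by log2 change where all 4 colonies moved the same way. Where fewer than 6 passed, the 6 with the smallest p were given as values that did not pass. Up to 4 passing members of each list were added, with dual oxidases, lysozyme and Down syndrome cell adhesion molecules whatever their p. The genes with the largest shares of reads, and those named from other fits of the 075 comparison, were chosen after their values were seen. The comparisons, tests, lists, named-gene rule and most alternatives were fixed before the data were examined.

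Alternatives were no filter, a stricter filter (mean count of at least 50), DESeq2 1.42.0 size factors or test, limma-trend on log2(RPKM + 1) or with a pseudocount of 0.1, quantile normalization, robust empirical Bayes, no block, only the 8 libraries compared, and each colony or exposure left out in turn. Fits without the K control and S 075 libraries, or also without L 161, and voom with library weights were added after the data were seen, as were the limits that define genes high in 2 libraries together and the gene length classes. Each count of called genes was compared with other splits of the libraries. The tests were tested on simulated data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots. The interaction of colony with each genotype was left out because no residual degrees of freedom remain.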

Results

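Gene expression was measured by poly(A) RNA sequencing in the guts of Bombus terrestris workers, a bumblebee, from 4 colonies labelled K, L, S and T. Workers were left unexposed or met 1 of 3 genotypes, 068, 075 and 161, of Crithidia bombi, a trypanosome that lives in the bumblebee gut. Each of the 16 libraries held RNA pooled from 3 workers that were 7 d old and were killed 18 h after exposure. There was 1 library per colony and exposure, so each exposure and each colony had 4. Library totals ran from 8.47 to 9.29 M reads, with a mean of 8.85 ± 0.22 M reads (SD, n = 16), and 9158 to 9721 of the 10635 genes had at least 1 read. Expression values are CPM, read counts scaled to the effective library size, with the SD over libraries, and log2 changes carry their standard error.

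Digestive enzymes were among the 10 genes with the largest shares of reads in these guts. The gene with the largest share, an alpha-glucosidase (LOC100646687, XM_003402177.1), which splits sugars such as sucrose and maltose, took 5.27% ± 0.97 of the reads (SD, n = 16). Shares of reads are not scaled by gene length. A second alpha-glucosidase (LOC100643731, XM_003395866.1) took 2.25% ± 0.27. An invertebrate carboxypeptidase A (XM_003402348.1) took 1.66% ± 0.37 and a protease annotated as plasma kallikrein (XM_003400059.1) 1.74% ± 0.27. Genes annotated as tripartite motif proteins took 2.05% ± 0.51 (LOC100648122, XM_003393487.1) and 1.83% ± 0.27 (LOC100643349, XM_003402694.1). The other 4 of these 10 genes had no product name or a weak database hit and took from 2.33% to 3.73% each. Together the 10 took 22.2% to 30.4% of the reads of a library. Lysozyme (XM_003400040.1), an antibacterial enzyme, stood at 1440 ± 223 CPM in controls and 1370 ± 290 CPM in exposed guts.

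The K control and L 161 libraries lay at the ends of the first principal component, and S 075 lay next to the K control. Principal component 1 held 34.1% of the variance and ran from the L 161 library at -51.92 to the K control at 54.26, with S 075 at 41.67 and S 161 at 32.21. Principal component 2 held 16% and its highest score was that of L 161, at 58.51. Median deviations of the cell cycle list, in log2 CPM, were 0.80 in the K control and 0.68 in S 075, and the highest of the other 14 libraries was S 161 at 0.20. The mitochondrial energy list had its lowest median in L 161, at -0.41, followed by the L control at -0.265. The list of epithelial renewal signals had its highest median in L 161, at 0.60. Fits without the K control, S 075 and L 161 are called fits without 3 libraries here, and were added after the data were seen.

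**Figure D1:**
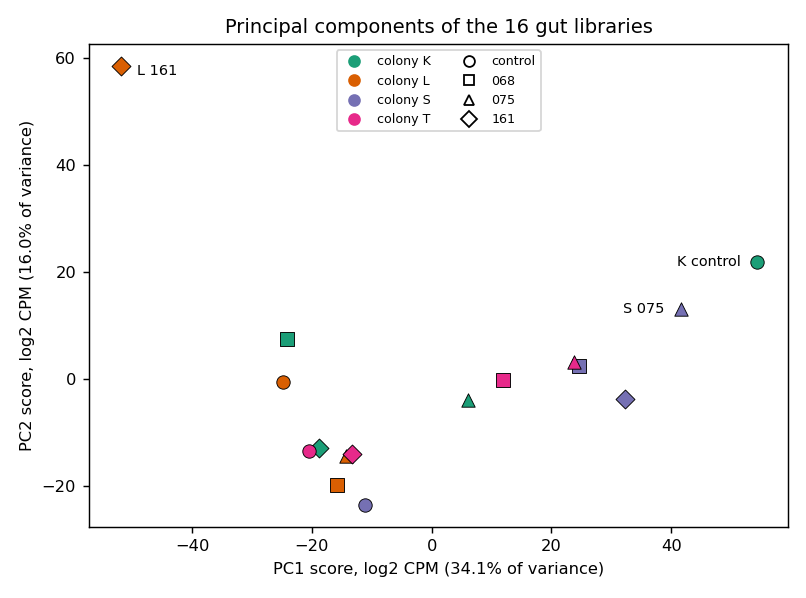
Scores of the 16 libraries on principal components 1 and 2 of log2 CPM, which hold 34.1% and 16% of the variance; colours are colonies and symbols are exposures, 1 point per library. The L 161 library lies at 58.51 on component 2, and the K control and S 075 libraries have the highest scores on component 1, at 54.26 and 41.67.

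The first question was whether exposure changed gut expression at all, over the 3 parasite genotypes together. No gene passed, and the genes nearest to passing are given as values. Trehalase (LOC100646078, XM_003400805.1), which splits the insect blood sugar trehalose into glucose, stood at 3710 ± 362 CPM in the 4 controls and 5610 ± 928 CPM in the 12 exposed libraries, with a log2 difference of 0.58 ± 0.15. ATP-dependent RNA helicase A (LOC100651168, XM_003398265.1) stood at 380.0 ± 133 and 729 ± 363 CPM, a log2 difference of 0.90 ± 0.23. Forkhead box protein C (LOC100643129, XM_003398850.1), a transcription factor, had 1.89 ± 1.05 and 0.612 ± 1.05 CPM, a log2 difference of -2.45 ± 0.64. It lay at or below the floor of 3 counts in 8 of 12 exposed libraries, and without L 161, at 3.59 CPM, the exposed mean was 0.342 CPM. A glial glutamate transporter of the solute carrier 1 family (XM_003395308.1) had 18.4 ± 6.18 and 12.8 ± 3.11 CPM. All 4 had the same direction in all 4 colonies and an adjusted p of 1 in edgeR's test.

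Further genes among the 6 with the smallest p were an oxidoreductase annotated only by its enzyme class (LOC100642272, XM_003402909.1) and a fatty acid elongase of type 6 (LOC100648002, XM_003402651.1). The oxidoreductase had 25.0 ± 2.94 CPM in controls and 40.7 ± 13.5 CPM in exposed guts. The elongase had no read in any of the 4 controls and reads in 10 of 12 exposed libraries. It lay at or below the floor of 3 counts in 5 of the 12. Its exposed mean of 0.931 CPM was at least 2.55-fold higher than the floor of 3 counts in a control library, taking reads as independent; the bound is lower if both mates of a pair were counted. Without S 075, the library with the highest value, the mean was 0.61 CPM and the bound 1.67-fold. Dicer (XM_003401907.1), the nuclease that makes small interfering RNAs, had a log2 difference of -0.57 ± 0.21 and was lower in 3 of 4 colonies. It passed when adjusted over the list alone (3 RNA interference genes, adjusted p = 0.0489) and not over all genes.

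Of 8406 genes tested with edgeR's quasi-likelihood test, 0 passed an adjusted p of 0.05, and 263 had an unadjusted p under 0.05, where 420 would by chance. DESeq2 also called 0 (293 at that level) and limma-trend 0 (191). In simulated data of the same depth, edgeR recovered 61% of genes changed 2-fold and 92% of those changed 4-fold; such power need not hold in these libraries. Without 3 libraries edgeR again called 0 genes, with 810 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0596.

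Ribosomal proteins, mitochondrial energy genes and the folding machinery of secreted proteins lay slightly higher in exposed guts as groups, although no member passed over all genes. Not every colony moved this way, as given at the end of this paragraph. Of 92 ribosomal protein genes, 69 were higher, with a median log2 difference of 0.07 (camera adjusted p = 0.000442 with a preset correlation; adjusted p = 0.559 with an estimated correlation). Of 54 mitochondrial energy genes, 38 were higher, with a median of 0.08 (adjusted p = 0.0027; adjusted p = 0.559 with an estimated correlation). Of 26 genes of the unfolded protein response and secretory pathway, 19 were higher, with a median of 0.10 (adjusted p = 0.0048; adjusted p = 0.559 with an estimated correlation). Of 56 heat shock proteins and chaperones, 35 were higher, with a median of 0.05 (adjusted p = 0.0102; adjusted p = 0.559 with an estimated correlation). Fry, which allows for the correlation of the members and does not compare a list with other genes, gave an adjusted p of 0.632 for each of these 4 lists. Without colony L none of the 4 passed and lipid metabolism did (adjusted p = 0.0284). Without 3 libraries the ribosomal list (adjusted p = 0.847) and the mitochondrial list (0.0687) no longer passed, while the secretory pathway (0.038) and chaperones (0.0127) did, but not with an estimated correlation (adjusted p = 0.81 and 0.724). Fits without a colony were run at the preset correlation and by no other list test. In colony T the ribosomal median deviation was 0.091 in the control and -0.007, 0.012 and -0.127 after 068, 075 and 161. In S the secretory pathway had 0.181 and -0.1, -0.065 and -0.046, and chaperones 0.082 and 0.012, -0.071 and 0.058. No list test removed the trend on gene length. The rank correlation of deviation with length ran from -0.23 in K 161 to 0.187 in L 161.

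**Figure D2:**
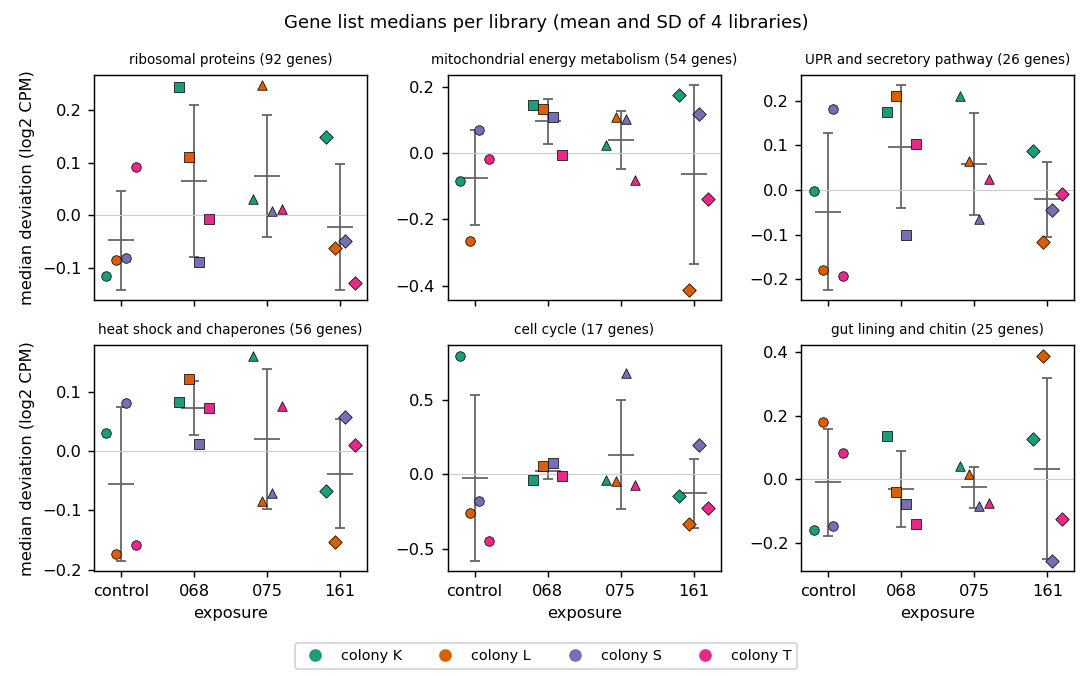
Median deviation of 6 gene lists from each gene's mean over 16 libraries, in log2 CPM, by exposure; points are libraries coloured by colony, and bars are the mean and SD of 4 libraries. The cell cycle panel shows the K control at 0.80 and S 075 at 0.68, and the mitochondrial panel shows L 161 at -0.41.

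Immune genes showed no shift with exposure in these tests. Among Toll pathway genes 11 of 15 were higher and among Imd pathway genes 1 of 6 (camera adjusted p = 0.294 and 0.458). JAK/STAT genes were higher in 2 of 8 cases (adjusted p = 0.587), pathogen recognition genes in 4 of 9 (0.553) and melanisation genes and serpins in 6 of 8 (0.69). The JNK list held 2 tested genes and the lysozyme list 1, too few for a list test. A list of 57 genes with immune or defence terms, added after the annotation was seen, gave an adjusted p of 0.992. Dual oxidases, which release oxidants against gut microbes, had log2 differences of -0.31 ± 0.28 (XM_003394502.1) and -0.14 ± 0.37 (XM_003400429.1). Genes annotated as Down syndrome cell adhesion molecule or its relative, immunoglobulin-family receptors, had -0.03 ± 0.25 (LOC100648077, XM_003402417.1), -0.18 ± 0.31 (XM_003394934.1) and 0.35 ± 0.32 (XM_003393930.1). A further 3 such genes fell below the count filter. Lysozyme had -0.08 ± 0.18. The receptor XM_003402417.1 changed sign under quantile normalization and without colony K, and lysozyme changed sign without colony T. The deposited descriptions named no antimicrobial peptide, relish, prophenoloxidase, transferrin or peptidoglycan recognition protein, so these were not measured by name.

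The remaining lists had no call for exposure over all 16 libraries. Gut lining and chitin genes were higher in 12 of 25 cases (adjusted p = 0.834), digestive proteases in 32 of 76 (0.742), and digestive carbohydrases and lipases in 17 of 36 (0.358). Detoxification genes were higher in 23 of 43 (0.134), oxidative defence in 16 of 27 (0.58), apoptosis and autophagy in 11 of 23 (0.742), and proteasome and ubiquitin in 85 of 193 (0.742). Nutrient transport genes were higher in 95 of 232 (0.69), lipid metabolism in 35 of 61 (0.062), and epithelial renewal signals in 5 of 15 (0.134). Cell cycle genes were higher in 6 of 17 (0.841, with a median of -0.05 and a test in the upward direction), circadian clock genes in 2 of 7 (0.987), and odorant-binding and chemosensory genes in 2 of 8 (0.655). Among markers of other tissues, muscle genes were higher in 3 of 6 (0.655), nervous system genes in 13 of 22 (0.458) and Malpighian tubule genes in 13 of 25 (0.992). Hemocyte and germ line markers had 2 tested genes each, and 0 of 2 and 1 of 2 were higher. The RNA interference list had 3, of which 0 were higher. Without 3 libraries camera called 4 further lists: the cell cycle higher (adjusted p = 0.00514), and gut lining and chitin (0.00783), muscle markers (0.00984) and epithelial renewal (0.0286) lower. None held there with an estimated correlation (adjusted p = 0.431, 0.531, 0.53 and 0.531). Leaving out these libraries, chosen after the data were seen, moves the 4 lists in the directions called. The K control had the highest cell cycle median, at 0.796. L 161 had the highest gut lining and epithelial renewal medians, at 0.388 and 0.597, and a muscle median of 0.488, second to the T control at 0.502. Calls of these lists without 3 libraries, here and for single genotypes below, are not independent of that choice. Of 184 annotated biological processes, a set added after the annotation was seen, 3 passed camera: translation, protein folding and response to stress, all higher (adjusted p = 0.024 each, and 0.958 with an estimated correlation). For 068, 075 and 161 alone 4, 10 and 0 passed, and 0 with an estimated correlation. Lower among those for 075 were protein phosphorylation, regulation of cellular process, actin cytoskeleton organization, intracellular signal transduction, wing morphogenesis and oogenesis.

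Genotype 068 gave no gene past the threshold against controls. The nearest was a cytochrome P450 of the CYP6 family (LOC100647803, XM_003393800.1), from a family that detoxifies plant compounds and insecticides, at 0.487 ± 0.386 CPM in controls and 4.6 ± 3.39 CPM after 068 (log2 difference 3.10 ± 0.75). It was higher in 3 of 4 colonies and passed only when adjusted over the list alone (adjusted p = 0.0478). Alpha-B crystallin (XM_003393513.1), a small heat shock protein, had 146 ± 22.7 and 279 ± 58.9 CPM, and the cell polarity gene prickle (LOC100650810, XM_003396247.1) 7.81 ± 0.924 and 14.5 ± 4.24 CPM. Acid phosphatase (XM_003394387.1) had 108 ± 33.9 and 153 ± 25.3 CPM.

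For 068, edgeR called 0 of 8406 genes (250 at an unadjusted p under 0.05), DESeq2 0 (286) and limma-trend 0 (173). As groups, 78 of 92 ribosomal protein genes, 46 of 54 mitochondrial energy genes, 22 of 26 secretory pathway genes and 37 of 56 chaperones were higher than in controls. Camera gave adjusted p = 2.25e-05, 2.25e-05, 0.000145 and 0.000137 in that order, and 11 of 15 epithelial renewal signals were lower (adjusted p = 0.0365). Muscle markers were also lower in 5 of 6 cases, with a median of -0.17 and no call (adjusted p = 0.201). With an estimated correlation each of the 5 lists had an adjusted p = 0.465. Without colony L only the ribosomal list passed (adjusted p = 0.0223). Without 3 libraries the ribosomal list no longer passed (adjusted p = 0.434) and the other 4 did, but not with an estimated correlation (adjusted p = 0.729 for mitochondrial, 0.672 for secretory pathway, 0.435 for chaperone and 0.435 for epithelial renewal genes). Newly called there were the cell cycle, higher (0.00483), and gut lining (0.00901) and muscle markers (0.00307), lower, none of them with an estimated correlation (adjusted p = 0.319, 0.435 and 0.319).

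Genotype 075 gave no gene past the threshold in edgeR, and 5 genes higher than controls in DESeq2. Gamma-glutamyl hydrolase (LOC100651812, XM_003398756.1), which trims folate chains, had 4.02 ± 0.76 CPM in controls and 14.4 ± 9.61 CPM after 075, a log2 difference of 1.65 ± 0.37 in edgeR. RNA helicase A had 380.0 ± 133 and 913 ± 484 CPM (1.19 ± 0.27) and the oxidoreductase XM_003402909.1 had 25.0 ± 2.94 and 52.4 ± 15.4 CPM (1.04 ± 0.21). Stearoyl-CoA desaturase (XM_003395098.1), which makes monounsaturated fatty acids, had 1.31 ± 0.81 and 6.5 ± 4.66 CPM (2.11 ± 0.52). The ubiquitin ligase NEDD4 (LOC100646768, XM_003393090.1) had 21.9 ± 4.96 and 14 ± 2.81 CPM (-0.65 ± 0.17). The elongase XM_003402651.1, unread in controls, had reads in 3 of 4 libraries, not in L 075, and was at least 4.23-fold higher than the control floor, with the same limit on independent reads. Without S 075 the bound was 1.57-fold.

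For 075, edgeR called 0 of 8406 genes (266 at an unadjusted p under 0.05) and limma-trend 0 (214). DESeq2 called 5 (298), namely gamma-glutamyl hydrolase (adjusted p = 0.0206), RNA helicase A (0.018), the oxidoreductase (0.0152) and 2 others chosen after their values were seen. These were a gene annotated as a delta-8 fatty acid desaturase with a weak database hit (LOC100648100, XM_003397757.1, 0.0152) and a gene with no product name (LOC100644966, XM_003396598.1, 0.012). All 5 were higher in all 4 colonies. In each, S 075 had the highest of the 4 values after 075, level with K 075 for RNA helicase A at 1330 CPM. The gene with no product name had 3.71 CPM in the L control and 4.26 in L 075. None of the 5 was among the 10 genes called without 3 libraries, given next. Without the K control, S 075 and L 161 libraries edgeR called 10 genes, 9 of them higher. Among them, also chosen after their values were seen, was a prostaglandin-H2 D-isomerase (LOC100650878, XM_003395027.1) (adjusted p = 0.0414), whose 3 controls kept in that fit lay at or below the floor of 3 counts, so the size of its change was not measurable there. It was the only 1 of the 10 with the same direction in all 4 colonies. Of the 9 called higher, 4 were lower over all libraries, also chosen after their values were seen: ecdysteroid 2-hydroxylase (LOC100644009, XM_003394564.1, with a log2 difference of -0.41 over all libraries) and XM_003400213.1, XR_132279.1 and XM_003401390.1, which have no product name. In all 9 called higher, these 4 included, the K control, left out there, had the highest value of the 4 controls. That holds for the prostaglandin-H2 D-isomerase too, at 5.34 CPM in the K control.

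Among the lists for 075, 74 of 92 ribosomal protein genes, 21 of 26 secretory pathway genes and 38 of 54 mitochondrial energy genes were higher (camera adjusted p = 0.000127, 0.0329 and 0.0329). These tests did not remove the trend on gene length. Its rank correlation was -0.021, -0.228, -0.089 and -0.104 in the 075 libraries of K, L, S and T, and 0.063, 0.155, -0.105 and 0.033 in their controls. With the trend removed, ribosomal medians were 0.03, 0.14, -0.061 and -0.04 after 075, from 0.031, 0.247, 0.008 and 0.012. In controls they were -0.129, -0.028, -0.127 and 0.067, from -0.115, -0.085, -0.081 and 0.091. Epithelial renewal signals were lower in 11 of 15 cases (adjusted p = 0.0478), and muscle markers in 4 of 6, with a median of -0.12 and no call (adjusted p = 0.347). Both lists had their highest control median in the T control, at 0.36 and 0.50. With an estimated correlation each of the 4 called lists, of ribosomal, secretory pathway, mitochondrial and epithelial renewal genes, had an adjusted p = 0.652. Without colony L none of these 4 passed and lipid metabolism did (adjusted p = 0.01). Without 3 libraries none of the 4 passed (adjusted p = 0.839, 0.0993, 0.45 and 0.0993 in the order above). Newly called there were the cell cycle (0.0118) and chaperones (0.0452), higher, and gut lining (0.0452), lower, none of them with an estimated correlation (adjusted p = 0.539, 0.587 and 0.587).

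Genotype 161 gave no gene past the threshold and no list. The smallest p belonged to the glutamate transporter XM_003395308.1, at 18.4 ± 6.18 CPM in controls and 12.1 ± 4.62 CPM after 161 (log2 difference -0.62 ± 0.18). TRAF-interacting protein (XM_003396063.1) had 9.18 ± 1.82 and 5.58 ± 2.94 CPM, and the mitochondrial protease HtrA2 (LOC100651265, XM_003401169.1) 29.0 ± 3.06 and 38.8 ± 6.17 CPM. A shared subunit of RNA polymerases I and III (XM_003402986.1) had 2.09 ± 0.808 and 0.881 ± 0.339 CPM, and DAAM (LOC100650848, XM_003397781.1), an actin-nucleating formin, had 25.8 ± 9.2 and 16.5 ± 1.19 CPM. Trehalase had 5620 ± 662 CPM after 161. edgeR called 0 of 8406 genes (166 at an unadjusted p under 0.05), DESeq2 0 (198) and limma-trend 0 (147). Ribosomal protein genes were higher in 49 of 92 cases. Without colony T camera called detoxification (adjusted p = 0.0386) and ribosomal proteins (0.0053), both higher, at the preset correlation; an estimated one was not run for that fit. Without 3 libraries it called the cell cycle higher and gut lining lower (adjusted p = 0.0249 each; adjusted p = 0.646 with an estimated correlation), and both lists had the opposite direction over all 16 libraries. The comparisons of 068, 075 and 161 with controls share the same 4 control libraries, so their lists are not independent.

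The next question was whether the 3 parasite genotypes differed from each other in the guts of their hosts. The DnaJ chaperone DNAJB1 (LOC100645002, XM_003395466.1) had 201 ± 35.9 CPM after 068, 180.0 ± 73.1 after 075 and 118 ± 13.8 after 161. The TATA-box binding protein (LOC100649431, XM_003402742.1) had 55.4 ± 8.91, 44.4 ± 12.4 and 74.5 ± 21.6 CPM, and the ubiquitin ligase SH3RF (LOC100644423, XM_003402626.1) 24 ± 2.72, 21.4 ± 4.75 and 34.1 ± 7.93 CPM. Lactosylceramide 4-alpha-galactosyltransferase (LOC100650768, XM_003396646.1), an axonemal dynein heavy chain (XM_003395900.1) and the microtubule linker CLIP1 (XR_132016.1) completed the 6 genes with the smallest p. None passed. edgeR's F-test called 0 of 8406 genes (134 at an unadjusted p under 0.05, where 420 would by chance), DESeq2 0 (166) and limma-trend 0 (115). In simulated data edgeR recovered 56% of genes changed 2-fold in 1 genotype. The simulation held no library standing apart, so such power need not hold in these libraries. Between pairs of genotypes edgeR called 0 for 075 against 068 (77), 0 for 161 against 068 (153) and 0 for 161 against 075 (312). DESeq2 called 0 in each pair (92, 171 and 364), as did limma-trend (61, 140 and 222).

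Colonies differed from each other in 39 genes past the threshold, 26 of them with a product name. Of 100 splits of the libraries, the real one included, 5 called at least as many, so chance was not excluded for the count as a whole. The log2 range over colony means had a median of 1.92 and ran from 0.71 to 5.04. Glyoxylate/hydroxypyruvate reductase (LOC100647868, XM_003398972.1), a metabolic enzyme of glyoxylate breakdown, had 288 ± 37.5 CPM in colony K and 192 ± 4.2 in S, against 18.3 ± 2.21 in L and 17.9 ± 3.65 in T (adjusted p = 6.43e-10). Valyl-tRNA synthetase (LOC100649646, XM_003402964.1), which loads valine for translation, had 1.57 ± 0.578 CPM in T and 24.7 ± 9.11 to 51.4 ± 14.4 elsewhere (adjusted p = 6.15e-05). Serpin B (XM_003399140.1), from a family of protease inhibitors, had 19.2 ± 6.63 CPM in S and at most 2.03 ± 0.785 in the others (adjusted p = 9.68e-05).

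Metabolic and receptor genes were among the rest. Lactosylceramide 4-alpha-galactosyltransferase had 12.8 ± 3.61 and 15.0 ± 3.37 CPM in S and T against 3.13 ± 1.06 and 2.73 ± 1.0 in K and L. Kynurenine/2-aminoadipate aminotransferase (XM_003393468.1) had 14.4 ± 5.69 CPM in K and 0.673 ± 0.367 in T. The tetraspanin-type gene transmembrane 4 superfamily member 2 (LOC100651747, XM_003393594.1) had 78.1 ± 19.6 CPM in K and 6.03 ± 1.33 in L. An NMDA-type glutamate receptor subunit (XM_003394411.1) had 0.931 ± 1.0 CPM in K and 10.5 ± 4.98 to 17.0 ± 5.12 elsewhere (adjusted p = 0.0121). The axonemal dynein XM_003395900.1 had 73.4 ± 23.1 CPM in K and 147 ± 30.8 in T, and a glucuronosyltransferase of proteoglycan synthesis (LOC100643292, XM_003398282.1) 38.5 ± 2.78 in S and 75.9 ± 6.42 in T.

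Fixed lists gave further colony differences. Among 76 digestive proteases 2 passed over all genes and 11 when adjusted over the list alone, with trypsin (LOC100646811, XM_003402868.1) at 364 ± 38.7 CPM in K and 149 ± 15.4 in S (adjusted p = 0.00492) and trypsin XM_003400060.1 at 752 ± 80.9 in T and 391 ± 32.3 in S. Carboxypeptidase A2 (XM_003400055.1) and chymotrypsin (LOC100642698, XM_003398194.1) passed only adjusted over the list alone (adjusted p = 0.0248 for both). Of 43 detoxification genes 1 passed over all genes and 4 adjusted over the list alone. The cytochrome P450 CYP28 (LOC100649871, XM_003393818.1) had 213 ± 29.2 CPM in T and 393 ± 43.9 to 483 ± 65.4 elsewhere (adjusted p = 0.00197). The others were CYP9 (XM_003393328.1, 2350 ± 195 CPM in K and 1490 ± 115 in S), CYP6G (XM_003394208.1) and CYP6 (XM_003400081.1), with adjusted p = 0.0181, 0.0288 and 0.0354 over the list. Of 15 Toll pathway genes 1 passed over all genes and 2 adjusted over the list alone: the gene annotated as toll-like receptor TLR3 (XM_003396806.1) had 43.2 ± 9.26 CPM in L and 14.4 ± 3.9 in T (adjusted p = 0.0158), and a second so annotated (LOC100651402, XM_003395847.1) had 10.2 ± 3.81 in K and 4.02 ± 1.28 in T.

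Nutrient transport, lipid metabolism and lipase genes also differed. A facilitated trehalose transporter (LOC100646248, XM_003402640.1) had 417 ± 54.9 CPM in K and 686 ± 118 in L (adjusted p = 0.0462), and a fatty acid elongase (LOC100645831, XM_003395722.1) 2.94 ± 1.89 in T (adjusted p = 0.0499), while its value in S lay below the floor of 3 counts. Transporters of solute carrier family SLC6 (XM_003400665.1) and SLC17 type (XR_132399.1) passed adjusted over the list alone, at 169 ± 24.3 CPM in K against 90.9 ± 12.9 in T and 30.9 ± 9.74 in K against 11.9 ± 4.44 in T. An sn1-specific diacylglycerol lipase (XM_003399904.1) had 34.5 ± 4.5 CPM in S and at least 59.8 ± 12.6 elsewhere, and a triacylglycerol lipase (LOC100644110, XM_003402157.1) 20.3 ± 2.71 in K and at most 13.1 ± 2.02 elsewhere; both passed adjusted over the list alone. No list was over-represented among the 26 described colony genes, with a smallest adjusted p of 0.577 by Fisher's exact test.

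**Figure D3:**
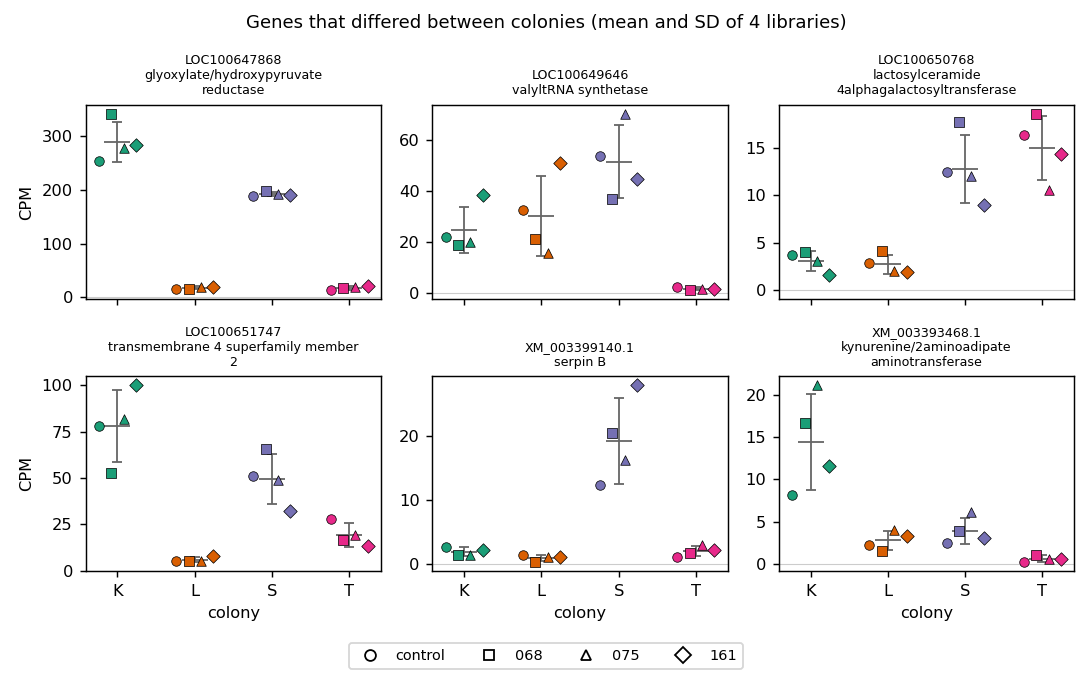
CPM of 6 genes that differed between colonies in edgeR's F-test; points are libraries, symbols are exposures, and bars are the mean and SD of 4 libraries per colony. Glyoxylate/hydroxypyruvate reductase stands at 288 and 192 CPM in K and S and at 18.3 and 17.9 in L and T.

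The colony test fitted exposure as a block and had 855 genes at an unadjusted p under 0.05. DESeq2 called 233 genes, voom with library weights 94, and the fit without the exposure block 73. Leaving out 1 exposure gave 83 without the controls, 14 without 068, 15 without 075 and 16 without 161, and the 2 fits without the K control and S 075, or also without L 161, gave 60 and 119.

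The last question was whether the response to exposure differed between colonies, the interaction of colony and exposed state. edgeR called 142 genes, in 134 of which the K control library had the highest value of all 16, and without colony K it called 0 (327 at an unadjusted p under 0.05). Each colony had 1 control library, so the spread among controls did not enter the test and these calls do not show that responses differed. Sterol O-acyltransferase (LOC100647632, XM_003398805.1), which stores cholesterol and other sterols as esters, had 145 CPM in the K control and 14.2 ± 2.05 in the 3 exposed K libraries, against 10.2 and 47.1 ± 19.8 in colony S (adjusted p = 0.00552). Breakpoint cluster region protein (LOC100650685, XM_003396327.1) had 76.3 and 19.2 ± 2.15 CPM in K and 12.1 and 39.1 ± 2.11 in S (adjusted p = 0.00552). Aminopeptidase N (XM_003402223.1), a digestive enzyme of the gut brush border, had 334 and 12.5 ± 4.66 CPM in K and 9.25 and 99.8 ± 61.4 in S (adjusted p = 0.0207).

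Cell division genes made up part of the set. Kinesin KIF20/KIF23 (XM_003393906.1) had 38.9 CPM in the K control and 2.19 ± 0.347 in exposed K libraries, inner centromere protein (LOC100649557, XM_003402887.1) 87.8 and 4.31 ± 0.448, and histone H3 (LOC100645858, XM_003392921.1) 76.8 and 5.21 ± 1.3. Of 17 cell cycle genes 2 passed over all genes, MAD2 (LOC100649509, XM_003398252.1) at adjusted p = 0.0207 and cyclin B (XM_003398885.1) at adjusted p = 0.0326, and 7 adjusted over the list alone, cyclin E (LOC100643771, XM_003397723.1) and a kinetochore protein (LOC100645484, XM_003395142.1) among them. The cell cycle list was not over-represented among the 87 described interaction genes (adjusted p = 0.731, Fisher's exact test). Median deviations of the list were highest in the K control and S 075 libraries, as given above.

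Genes of transport, detoxification and protein turnover were also called, although none of these lists was over-represented (smallest adjusted p = 0.82, Fisher's exact test). A facilitated trehalose transporter (XM_003400510.1) had 78.7 CPM in the K control and values below the floor of 3 counts in exposed K libraries, and of 232 nutrient transport genes 6 passed over all genes and 8 adjusted over the list alone. CYP15A1 (LOC100642209, XM_003396659.1; the family CYP15 makes juvenile hormone in insects) had 60.6 CPM in the K control and reads in none of the other 3 controls, and a second CYP15A1 (LOC100647578, XM_003396620.1) had 20 CPM there and 1.53 ± 1.02 in exposed K libraries. Of 43 detoxification genes 2 passed over all genes and 4 adjusted over the list alone, among them CYP6G (XM_003399938.1) and CYP18A1 (LOC100642897, XM_003400126.1). Of 193 proteasome and ubiquitin genes 4 passed, the conjugating enzyme UBE2Q (XM_003394743.1), MYCBP2 (XM_003396565.1), RNF139 (XM_003401132.1) and UBR3 (LOC100648492, XM_003402030.1). Serpin B XM_003399138.1 had 83.8 CPM in the K control and 2.6 ± 0.749 in exposed K libraries (adjusted p = 0.0284). Of 76 genes on the digestive protease list 3 passed, with trypsin (LOC100645023, XM_003400228.1) at 63.7 and 0.53 ± 0.386 CPM. Another was a carboxypeptidase N regulatory subunit (LOC100648620, XM_003393729.1) at 261 and 335 ± 29.6, which the list matched by its name only. It was 1 of 6 called genes that were higher in exposed K libraries than in the K control.

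The rest of the named set held lipid, signalling and transport genes. A triacylglycerol lipase (LOC100645916, XM_003398388.1) had 23.2 CPM in the K control and 1.86 ± 0.676 in exposed K libraries, and the large subunit of microsomal triglyceride transfer protein (XM_003400299.1), which loads lipid onto lipoproteins, 95.3 and 16 ± 4.01. TRIM71 (XM_003400466.1) had 57.9 and 0.774 ± 0.557 CPM, PAX-interacting protein PTIP (XM_003397124.1) 370.0 and 35.1 ± 8.46, a serine/threonine kinase (XM_003397204.1) 40.7 and 6.0 ± 0.474, and a Kruppel-like factor (LOC100642205, XM_003396015.1) 4.55 and values below the floor. A voltage-dependent calcium channel (XM_003394356.1) had 18.5 and 1.78 ± 0.341 CPM, and carriers XR_131825.1, XM_003400655.1 and XM_003396933.1 had adjusted p = 0.0221, 0.0221 and 0.0227. Passing adjusted over the list alone were TAB1 (XM_003395277.1, Imd list of 6, adjusted p = 0.0358), PIAS2 (LOC100650762, XM_003395430.1, JAK/STAT list of 8, 0.0407), a SOX group B factor (XM_003398882.1, 0.043), calreticulin (LOC100643307, XM_003403152.1, 0.0404) and integrin beta (XM_003393164.1, a hemocyte marker, 0.00522).

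**Figure D4:**
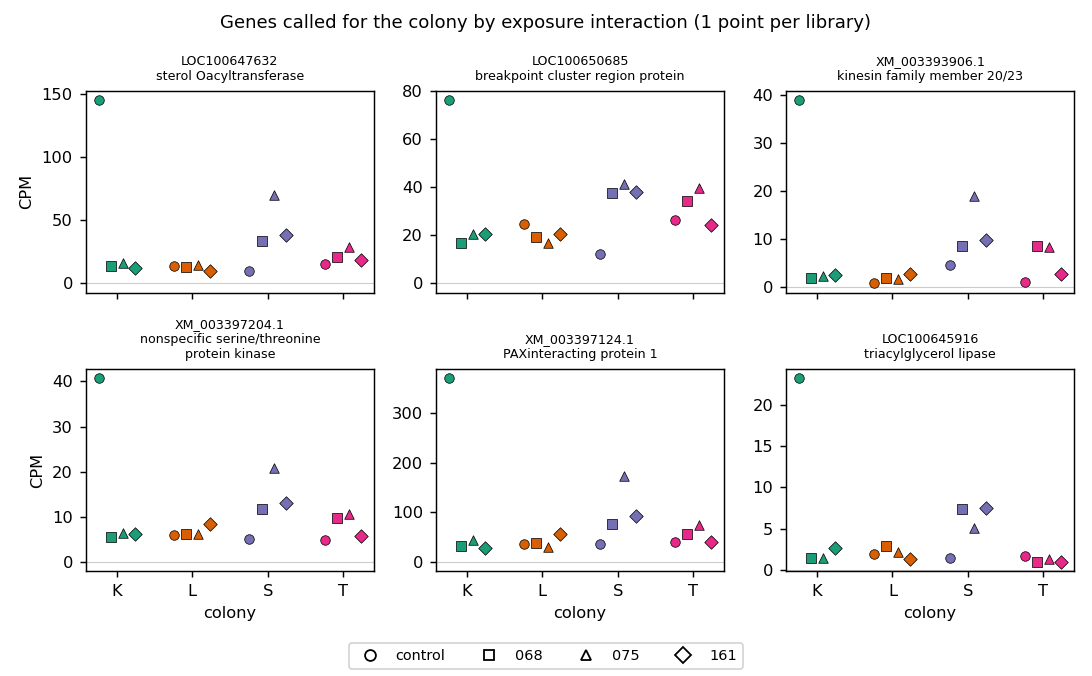
CPM of 6 genes called for the colony by exposure interaction, 1 point per library; colours are colonies and symbols are exposures. Sterol O-acyltransferase stands at 145 CPM in the K control and at 14.2 ± 2.05 in the 3 exposed K libraries.

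The test assumed that the lone controls vary like the exposed libraries, and edgeR had 902 genes at an unadjusted p under 0.05. It called 0 genes without the K control and S 075 (284 at that level), as also without L 161 (713), while DESeq2 and limma-trend over all libraries called 320 and 231. Without colonies L, S and T the counts were 345, 55 and 122. In simulated data, which held no library standing apart, edgeR recovered 12% of genes with a 4-fold interaction and 0% with a 2-fold one. The interaction of colony with each parasite genotype had no residual degrees of freedom and was not tested by gene.

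Responses of different colonies to the same parasite genotype were no more alike than responses to different genotypes. The mean correlation across 7553 genes of log2 changes from the colony's own control was -0.07 for 18 pairs of colonies facing the same genotype and -0.05 for 36 pairs facing different ones. The difference of -0.02 had a one-sided exact permutation p = 0.898 over 216 relabellings. Genes are not independent replicates, so the test permutes libraries. Changes from the control in colonies K and S had a mean correlation across genes of -0.47 (-0.62 to -0.32). All of these pairs subtract the same K control and the same S control, so they amount to about 1 contrast and do not show opposite responses.

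The shares of the spread taken by colony and by exposure were not above chance over all 16 libraries. Colony took a median of 24% of a gene's sum of squares and exposure 12.8%, and the remainder held 60%. Equal spread would give a mean share of 20% each. The observed shares are medians, which are not on the scale of a mean, so only the permutations compare them with chance. A permutation test with 100 relabellings gave p = 0.87 for exposure and p = 0.11 for colony. Leaving out colony K, L, S or T gave medians of 23.9%, 17.8%, 18% and 23.3% for colony, where equal spread would give a mean of 18.2% (permutation p = 0.04, 0.48, 0.27 and 0.16). Exposure took medians of 21.6%, 15%, 24% and 17.9% there, where equal spread would give a mean of 27.3% (permutation p = 0.48, 1, 0.51 and 0.78).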

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

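The splits of the libraries, the gene length test in L 161 and the test of the K control standing apart were set before their results were seen; the other tests here were chosen after. A library is given here when its gap to the nearest of the 4 libraries of its exposure exceeded Dixon's critical share of the range. Chance gives about 1 in 20 groups: 7 of 120 groups of library measures and list medians were found (6 by chance), and 43 of 360 groups of named genes (18 by chance). Many named genes were picked for calls that rest on the K control, so the excess among genes is not independent evidence.

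Among list medians, in log2 deviation, these were ribosomal proteins in T control at 0.091 and L 075 at 0.247, pathogen recognition in L 068 at -0.263, detoxification in T 075 at -0.115 and the cell cycle in S 075 at 0.681. In L 161 they were melanisation and serpins at 0.3 and epithelial renewal at 0.597.

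In the K control, values in log2 CPM lay apart from the other 3 controls. They were 7.19 for sterol O-acyltransferase XM_003398805.1, 5.35 for the kinase XM_003397204.1, 8.53 for XM_003397124.1, 4.55 for the lipase XM_003398388.1 and 5.86 for TRIM71 XM_003400466.1. Aminopeptidase N XM_003402223.1 had 8.39, inner centromere protein XM_003402887.1 had 6.46, histone H3 XM_003392921.1 had 6.27, XM_003400299.1 had 6.58 and the calcium channel XM_003394356.1 had 4.23. Cell cycle genes were MAD2 XM_003398252.1 at 4.06, cyclin B XM_003398885.1 at 4.81 and cyclin E XM_003397723.1 at 4.12. CYP15A1 XM_003396659.1 had 5.93, the SOX gene XM_003398882.1 had 3.92, RNF139 XM_003401132.1 had 5.38, and the transporters XR_131825.1, XM_003400655.1 and XM_003400510.1 had 3.84, 3.89 and 6.3. Lower than the other controls were the NMDA receptor XM_003394411.1 at -1.62 and the trehalose transporter XM_003402640.1 at 8.87.

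In other libraries of colony K the NMDA receptor XM_003394411.1 had -0.16 (K 075) and 1.38 (K 161), the lipase XM_003402157.1 had 4.3 (K 068) and 4.45 (K 161), and XM_003402640.1 had 8.74 (K 068). In S 075 the oxidoreductase XM_003402909.1 had 6.24, DAAM XM_003397781.1 had 4.36, the lipase XM_003399904.1 had 5.03, the transporters XR_131825.1 and XM_003396933.1 had 2.53 and 5.93, and MYCBP2 XM_003396565.1 had 5.87. In L 161 trehalase XM_003400805.1 had 12.69, integrin XM_003393164.1 had 1.82 and lysozyme XM_003400040.1 had 9.31. Single values were gamma-glutamyl hydrolase XM_003398756.1 at 1.64 in L control, valyl-tRNA synthetase XM_003402964.1 at 0.75 in T 161, CYP28 XM_003393818.1 at 7.99 in T control, and kinesin XM_003393906.1 at 3.32 and aminopeptidase N XM_003402223.1 at 6.39 in S 161. The last were CYP6G XM_003394208.1 at 9.43 in T 068, XM_003400510.1 at 1.17 in S 068 and dual oxidase XM_003394502.1 at 2.6 in T 075.

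The interaction test called 142 genes, but with 1 control library per colony it cannot show that responses differed. In 139 of them the K control lay farther from the other controls than the exposed K mean lay from the other exposed libraries. This comparison cannot decide whether 1 library stood apart. The genes were called on the difference of exposed from control, and a single library varies more than a mean of several. Without colony K the test called 0 genes in edgeR (327 at an unadjusted p under 0.05). A response peculiar to workers of colony K stays open: with 1 control library, colony and library cannot be told apart. Chance was not excluded, since 17 of 100 splits called at least 142 genes, and the highest, with 1264, points to a structure of the samples because it took the K control and L 161 as controls.

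In the K control and S 075 together, 71 genes lay at least 2-fold above all other libraries at 5 RPKM or more, with 1.08% and 0.63% of reads against at most 0.07% elsewhere, and the next of 120 pairs of libraries shared 4. Library size as a cause common to both is argued against, since the S 075 total ranked 11 of 16, although the K control total ranked 2. The count of pairs that share as many, 1, is fixed by the choice of this pair. The gap from 71 to the 4 of the next pair is not. It argues against unrelated high genes in 2 libraries for the 71 genes as a set, and names no source. Tissue with dividing, germ or other cells carried along with the gut may be a source. In both libraries 7 of 17 cell cycle genes and 0 of 3 expressed germ line markers were above all 14 others. The 2 hemocyte markers had a median of 1.042 in the K control, the highest of 16, and 0.349 in S 075, below T 075 at 0.466. These markers are too few to decide. The 2 libraries come from different colonies and exposures, so no factor of the design names them, and no explanation from the design was tested.

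In L 161, mitochondrial energy genes had a median of -0.413, and genes under 2 kb a median of -0.219 against 0.144 for those of 4 kb or more. With the trend on length removed, the energy median was -0.216 (SE 0.123), so a length bias could be part of it and is not decided. The low energy median was not peculiar to L 161. The unexposed L control had -0.265, and -0.214 (SE 0.046) with the trend removed, while L 068 and L 075 had 0.132 and 0.108 before removal. Library size is argued against, since the total ranked 12 of 16. Exposure to genotype 161 is argued against as the whole cause, since 0 of the other 3 libraries of 161 had a median below -0.2. RNA quality was not given and was not tested.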

How the results depend on the processing

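Fits without the K control and S 075 libraries, or also without L 161, and voom with library weights were chosen after the data were seen. The counts of 0 for exposure, 068, 161 and the differences between genotypes stayed at 0 under every alternative run. For 075 DESeq2 called 5 and the fit without 3 libraries 10, where edgeR called 0 (266 at an unadjusted p under 0.05).

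The block matters for the colonies: without the exposure block, 73 genes were called in place of 39. DESeq2 called 233, voom 94, and the fits without 2 and 3 libraries 60 and 119. Leaving out 1 exposure gave 14 to 83. The cause was not tested.

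For the interaction, 142 in edgeR, the stricter filter gave 85, quantile normalization 84, DESeq2 320 and limma-trend 231. Leaving out 1 colony gave 0 to 345, and without 2 or 3 libraries 0 and 0 were called. Without the K control its colony has no interaction term. Beyond that, the cause was not tested. No fit without the block and no voom fit was run for it.

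For response similarity, -0.0181, every alternative stayed negative. In sums of squares, leaving out 1 colony gave 17.8% to 23.9% for colony, 15.0% to 24% for exposure and 49.1% to 61.6% for the remainder, partly because fewer libraries change the share that equal spread gives.

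Lists passing fell to 0 with an estimated correlation and to 0 with fry for exposure, 068 and 075. Leaving out 1 colony gave 1 to 5 lists for exposure, 1 to 7 for 068, 1 to 4 for 075 and 0 to 2 for 161, and without 3 libraries 6, 7, 3 and 2 lists passed, not all the same lists as before. The cause was not tested.

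Signs changed for lysozyme (XM_003400040.1, exposed versus control, -0.184 to 0.038 with 1 colony left out) and the adhesion molecule (XM_003402417.1, exposed versus control, -0.135 to 0.151; 0.018 with quantile normalization, 0.235 and 0.103 without 2 and 3 libraries). Neither passed. Over the other values of named genes, 1233 stayed on their side of the threshold, 55 passed newly and 166 no longer passed. For the lists that passed over all libraries, 46 values still passed and 58 did not; lists that passed newly are not in these counts.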

Other observations

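The splits of the libraries were all set before their results were seen, and the weights were chosen after. For the counts of 0, every split called at least as many, so these say nothing against chance: 100 of 100 for exposed against control, 100 of 100 between genotypes, and 35 of 35 for each comparison of 1 genotype with controls or with another genotype. The highest other split called 52 genes for exposure, 2 for 068, 5 for 075, 146 for 161 and 1 between genotypes. For the pairs of genotypes it called 1 for 075 against 068, 0 for 161 against 068 and 0 for 161 against 075, by edgeR (77, 153 and 312 at an unadjusted p under 0.05 in the real split). A split that calls 52 genes where the real one calls 0 points to a structure of the samples. Splits for exposure and between genotypes moved labels within colonies only. Those for 1 genotype against controls or another genotype did not, so labels can be uneven over colonies there. The 146 for 161 comes from these and is not comparable with the 52 or with the real split. For the colonies, 5 of 100 splits called at least the 39 real genes and the highest other called 127, so chance was not excluded for the count as a whole.

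Correlations across genes between libraries of 1 colony were taken after each gene's mean over the 4 libraries of an exposure was removed. The mean r was 0.259 in L, 0.13 in S, 0.104 in T and 0.003 in K. Single pairs ran from -0.102 to 0.457 in L, -0.298 to 0.485 in S, -0.068 to 0.402 in T and -0.223 to 0.3 in K. Genes are not independent replicates. Estimated library weights were lowest in L 161, at 0.21, and the K control, at 0.34. S 075 had a weight of 1.32, so the weights do not set it apart.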
